A study of Mus musculus and Rattus norvegicus with 92 samples.

How the data were processed

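The series measured RNA in 5 experiments, 92 libraries in 21 groups. Whole hippocampus of aged mice was sequenced with polyA libraries after 6 days of infusion with young mouse CSF (YM-CSF) or artificial CSF (aCSF). Rat oligodendrocyte precursor cells (OPCs) were labelled with 4-thiouridine (s4U, 62.5 uM) for 1 h or 6 h in pooled young human CSF (YH-CSF) or aCSF and sequenced from the 3' end. In this SLAM-seq assay chemical conversion of s4U reads as T>C changes, so that T>C reads are meant to mark RNA made during the labelling. Nuclei of OPCs and of oligodendrocytes (OLs) were sorted from mouse hippocampus by Olig2 level and sequenced with Smart-seq2.

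Per the labels, the hippocampus table holds counts, raw reads per gene symbol (24411 symbols). The 2 culture tables that the authors deposited hold counts of all reads and counts of T>C reads for 15638 rat gene symbols. The read caller and the number of T>C changes that made a read count were not stated. For 749 of the 10438 culture genes with total counts in at least 6 libraries, which hold 17.1% of total and 16.2% of T>C reads, all counts were multiples of 1 whole number (4 for Tmem9, 5 for Stmn4, 16 for Fgfr2). The reason was not stated, and these counts were used as they are. The nuclei files that the authors deposited hold expected counts from RSEM for 45706 gene identifiers, 45143 of them with a symbol and 56 symbols shared by more than 1 identifier. Of these values 36.8% were not whole numbers, and all were rounded before the fits. The submitters' processing notes name bcl2fastq, STAR, FastQC 0.11.8, MultiQC 1.7, RSEM, R 3.6.1 and DESeq2 1.26.0 and the builds GRCm38 and Rnor_6.0, without saying which tool made which file. The name of the hippocampus table speaks of a mean that nothing explains, and its values were used as the counts they are. Gene positions come from a GRCm38 annotation.

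Groups followed the sample labels. The labels call the 16 h libraries given CSF of aged mice (AM-CSF) controls and the aged nuclei treated, and both were used by their fluid or age. The design text speaks of OPCs alone for the 1 h and 6 h injections, whereas the series also holds 16 OL libraries of that experiment. The labels do not say whether each library came from a separate animal or culture, so every p-value measures the spread between libraries alone. Each culture time was 1 plate.

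Counts were fitted in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood, robust, TMM factors, genes kept by filterByExpr on the groups). Hippocampus, culture total reads, culture T>C reads, OPC nuclei of the 1 h and 6 h injections, OL nuclei of the same injections, and OPC nuclei of 16 h had 1 fit each. For the age experiment OPC nuclei, OL nuclei and both together were fitted. 20 contrasts were tested, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold, and a gene past it is said to be called. The 3 contrasts at 16 h share their groups, so they are not independent. Log2 fold changes carry standard errors (SE) from the fit, and levels in CPM (counts scaled to the library total over the tested genes times its TMM factor) carry standard deviations (SD). For T>C reads of YH-CSF 1 h replicates 3 and 5 these factors were 0.566 and 0.436, which raises their CPM. P-values of genes are two-sided edgeR values unless another tool is named.

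Of the genes, 23 lists were fixed: immediate early genes, SRF targets and actin cytoskeleton, FGF and ERK feedback, OPC, committed premyelinating oligodendrocyte, myelin and mature oligodendrocyte, cholesterol synthesis, cell cycle, glucocorticoid response, NF-kB and acute phase, interferon and antigen presentation, heat shock, unfolded protein and integrated stress, microglia, astrocyte, neuron, endothelial cell and pericyte, choroid plexus, ependymal, meningeal fibroblast, ribosomal protein, erythrocyte and mitochondrially encoded genes. Each was tested with camera of limma 3.58.1 against the other genes at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Adjustment ran over the lists of a contrast. Lists with too few tested members in a contrast were left out of it, which gave 419 list tests. Mitochondrial and erythrocyte lists were therefore not used for the hippocampus, and these and the microglia, choroid plexus and ependymal lists not for the culture. Levels of a list per library, the mean log2 CPM of its members, were compared with two-sided exact permutation tests, adjusted over the lists of the contrast.

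Named genes are the 8 higher and 8 lower called genes of each contrast with the largest fold change, an average log2 CPM of at least 3 and groups that do not overlap (no such demand for interactions), passing over unnamed transcript models. Up to 4 called members of each list with at least 2 called members join them, as do Srf, Fgf17, Fgfr1, Fgfr2, Fgfr3, Pdgfra and Mbp in every contrast. The text gives a part of these genes, so that a gene left out of a contrast may still have been measured. Where fewer than 5 genes were called, the 3 named ones of smallest p in each direction are given as values, apart from genes not used here. List members named with a list that was called were chosen after their values were seen. For genes at 0 in a whole group, the fold is a bound against a floor of 3 counts over the group. Intervals and floors cover counting error only. The contrasts, lists, named-gene rule and main alternatives were chosen before the data were examined.

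Alternatives were RLE size factors, no low-count filter, the replicate number as a block, limma-voom with sample quality weights, DESeq2 1.42.0, each fit with the 2 compared groups alone, each library left out, and T>C counts scaled by total reads. Added after the data were seen were fits without the libraries that stand apart and, for the age experiment, fits with a 2-part split of its libraries as a term, and for the culture a fit with the counts of each gene divided by such a whole number. A library stands apart where its mean correlation with the others of its fit lies more than 3 median absolute deviations below the median, with at most 2 per fit. Genes ranked by p in the culture and age contrasts were also tested as lists in the CSF contrasts. Equal numbers were taken to pair aged OPC and aged OL nuclei alone, since there the residuals of all 3 pairs of libraries with 1 number correlated at over 0.1 (0.23 to 0.32), while the labels give no pairs. No main fit used these pairs, and the splits of the libraries did not keep them together. The number entered only as a block among the alternatives. The block of the joint OPC and OL fit used age and number, and so also set young OPC and OL libraries of equal number together. Up to 100 other splits of the libraries were fitted per contrast.

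Pairs of libraries were checked for duplicates by a chi-square per gene, whose lowest value in any group was 5.86. The pipeline was tested on simulated data with planted changes. In data simulated like the hippocampus 49.3% of planted 1.5-fold changes and 77.4% of 2-fold changes were called. For culture total reads at 1 h 12.3% of planted 2-fold and 43.1% of 4-fold changes were called, and for T>C reads 0% of either. For OPC nuclei aged against young 4.5% of 2-fold changes were called, for OL nuclei aged against young 8.1%, for OL nuclei at 1 h 44.1%, for OPC nuclei at 1 h 3.1%, and for OPC nuclei at 16 h with YM-CSF 0%. Of the calls made in these simulations 8 of 44 (18.2%) were false for OL nuclei aged against young, 4 of 40 (10%) for culture total reads at 1 h, 2 of 26 (7.7%) for OPC nuclei aged against young and 12 of 160 (7.5%) for the hippocampus, above the 5% aimed at, and at most 4.8% in the other contrasts with calls. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.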

Results

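The data cover cerebrospinal fluid (CSF) given to aged mice or to cultured precursor cells, and the ageing of the oligodendrocyte lineage. Whole hippocampus of aged male mice was measured after infusion of young mouse CSF (YM-CSF, n = 7) or artificial CSF (aCSF, n = 8), at 8.57 to 12.4 M reads per library and 16447 to 16978 genes detected. Rat oligodendrocyte precursor cells (OPCs) were cultured with young human CSF (YH-CSF) or aCSF for 1 h (n = 5 and 4) or 6 h (n = 5 and 5), at 6.41 to 13.7 M reads, of which 0.187 to 1.68 M carried T>C changes. Nuclei of OPCs (Olig2-high) and oligodendrocytes (OLs, Olig2-low) came from young and aged hippocampi (OPC n = 4 and 4, OL n = 4 young and 3 aged), at 5.2 to 32.2 M reads. Further nuclei came from 18-month-old mice 1 h or 6 h after 3 ul of YM-CSF or aCSF in a lateral ventricle (n = 4 per group, 6.97 to 31.9 M reads for OPCs and 5.66 to 16.1 M for OLs). OPC nuclei were also taken 16 h after aCSF (n = 3), YM-CSF (n = 4) or CSF of aged mice (AM-CSF, n = 4), at 8.88 to 29.8 M reads.

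The hippocampus after infusion addresses whether young CSF changes the oligodendrocyte lineage of aged animals. Genes of myelin-forming oligodendrocytes rose as a list with YM-CSF: all 24 measured members of the myelin list had a log2 fold change above 0, with a median of 0.65 (camera, adjusted p = 3e-13; adjusted p = 0.596 with an estimated correlation). Mbp, which encodes myelin basic protein, stood at 3460 ± 931 CPM (SD, n = 7) with YM-CSF and 2030 ± 790 CPM (n = 8) with aCSF, a log2 fold change of 0.77 ± 0.25 (SE). Myrf, a transcription factor that drives myelin genes, stood at 161 ± 40.9 against 95.1 ± 31.5 CPM, and Mag, a protein of the inner myelin face, at 338 ± 97.4 against 189 ± 80.9 CPM. Adjusted over the list alone 17 of the 24 genes passed, and 0 did over all genes tested. The mean level of the list per library was 6.95 ± 0.45 against 6.23 ± 0.55 log2 CPM (two-sided exact permutation test, p = 0.0193, adjusted p = 0.203). The aCSF replicates 7 and 8 stood apart from the other libraries, and without them this difference was 0.71. Precursor genes did not differ in the same way: the OPC list stood at 5.47 against 5.40 log2 CPM, and Pdgfra, the PDGF receptor of OPCs, at 57.9 ± 6.77 against 57.9 ± 8.24 CPM.

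**Figure D1:**
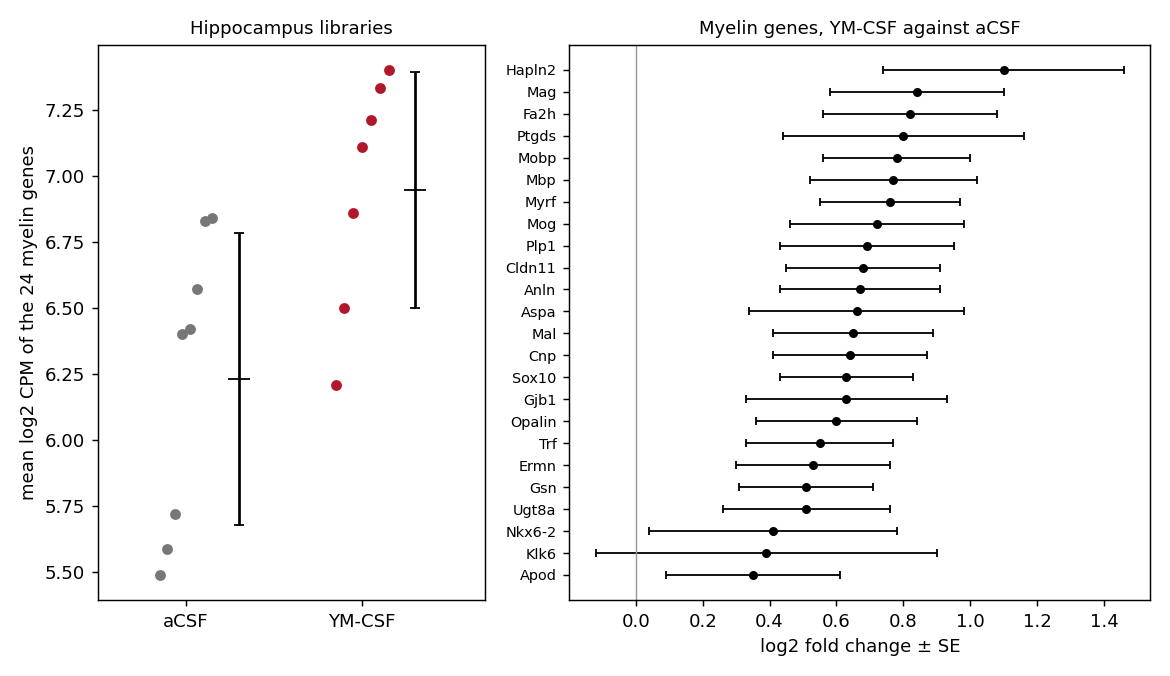
Left, mean log2 CPM of the 24 myelin genes in each hippocampus library, with the mean and SD of each group (aCSF 5.49 to 6.84, YM-CSF 6.21 to 7.40). Right, log2 fold change with SE of each gene, YM-CSF against aCSF.

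Other gene groups moved in the hippocampus by smaller steps. Genes of cholesterol synthesis fell as a list, with 22 of 24 members below 0 and a median log2 fold change of -0.24 (camera, adjusted p = 5.51e-06; adjusted p = 0.596 with an estimated correlation). Hmgcs1, which makes the precursor of mevalonate, stood at 161 ± 17.2 (n = 7) against 222 ± 50.8 CPM (n = 8), and 6 members passed adjusted over the list alone, 0 over all genes. Glucocorticoid response genes rose, with 15 of 17 above 0 and a median of 0.35 (adjusted p = 0.000204; adjusted p = 0.596 with an estimated correlation). Of these Ddit4, a stress-induced inhibitor of mTOR signalling, and Arrdc2 passed adjusted over the list alone, 0 over all genes. Astrocyte genes rose with 13 of 15 above 0 and a median of 0.19 (adjusted p = 0.00207; adjusted p = 0.596 with an estimated correlation). Endothelial genes rose with 15 of 16 above 0 and a median of 0.18 (adjusted p = 0.00507; adjusted p = 0.779 with an estimated correlation), a call lost without YM-CSF replicate 7 (adjusted p = 0.0616). Choroid plexus genes varied widely, at 2.89 ± 1.61 against 2.68 ± 1.39 log2 CPM.

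No single gene passed in the hippocampus: edgeR called 0 of 13961 genes (smallest adjusted p 0.15), with 2287 at an unadjusted p under 0.05, while DESeq2 called 134 and voom with quality weights 0. Without aCSF replicate 5 edgeR called 1. Among the smallest p were Rgs2, a regulator of G protein signalling (25.7 ± 1.6 CPM, n = 7, against 41 ± 7.88, n = 8; edgeR, adjusted p = 0.15), Klf2 (log2 fold change 1.04 ± 0.21) and Pou3f3 (0.80 ± 0.16). Ado was at 0.55 ± 0.11, Drc1 at -0.46 ± 0.08 and Dbpht2 at -0.85 ± 0.16. Srf, the serum response factor, was at 0.11 ± 0.11 (edgeR, adjusted p = 0.598), Fgfr1 at 0.26 ± 0.14, Fgfr2 at 0.48 ± 0.17 and Fgfr3 at 0.19 ± 0.11. Fgf17 had at most 17 counts in a library (0.163 ± 0.108 against 0.339 ± 0.438 CPM) and was not tested.

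The culture asks which genes young CSF acts on first in OPCs. Srf, whose protein drives actin and immediate early genes, rose at 1 h in total reads to 308 ± 150 CPM (SD, n = 5) with YH-CSF from 89.6 ± 17.2 CPM (n = 4) with aCSF, a log2 fold change of 1.78 ± 0.30 (SE; edgeR, adjusted p = 0.0452). The lowest YH-CSF library, at 165 CPM, lay above the highest aCSF library, at 111 CPM. In GRCm38 the mouse gene Srf (ENSMUSG00000015605) lies on chromosome 17 at 46548329 to 46556175 on the minus strand. Feedback genes of FGF and ERK signalling rose as a list, with 8 of 10 above 0 and a median of 0.44 (camera, adjusted p = 0.00699; adjusted p = 0.461 with an estimated correlation). Phlda1 stood at 520 ± 176 against 256 ± 14.2 CPM, Dusp6, a phosphatase of ERK, at 179 ± 63.1 against 82.4 ± 8.46 CPM, and Ccnd1, the cyclin D1 gene, at 2010 ± 770 against 1220 ± 270 CPM. In this list 4 genes passed adjusted over the list alone and 0 over all genes. The call of the list was lost without YH-CSF replicate 3 (adjusted p = 0.0664) or aCSF replicate 5 (0.0821).

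At 1 h Srf was the 1 gene called by edgeR of 10164 tested in total reads (1120 at an unadjusted p under 0.05), against 74 by DESeq2 and 3 by voom with quality weights. The call of Srf was lost in 6 of 9 fits that each left out 1 library: without aCSF replicate 1 (adjusted p = 0.332), 2 (0.188), 3 (0.436) or 5 (0.125) or YH-CSF replicate 2 (0.0531) or 3 (0.171), with log2 fold changes of 1.51 to 1.91 over the 9 fits. Without YH-CSF replicate 1 edgeR called 10 genes and without replicate 5 it called 2. The YH-CSF replicates 3 and 5 stood apart from the others, and without both Srf was at 1.21 ± 0.24 (adjusted p = 0.165). RLE size factors (0.0566), a fit of the 2 groups alone (0.859) and thinning of all libraries to the smallest total (0.053) also ended the call. So did the replicate number as a block, with which no gene was called. Lower with YH-CSF were Bcl7b (7.62 ± 3.11 against 30.1 ± 3.88 CPM; edgeR, adjusted p = 0.117) and the low-count genes Esrrg and Ginm1, which had 0 counts in all YH-CSF libraries (at least 43.3-fold and 37.7-fold lower over the group). Pdgfra was at -0.23 ± 0.20, Mbp at 0.47 ± 0.25 and Fgfr2 at 0.03 ± 0.52.

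At 6 h 3 lists were called in total reads that were not called there at 1 h. Of these only cholesterol synthesis was also called in the test between the times. Genes of cholesterol synthesis fell as a list with YH-CSF, with 22 of 23 members below 0 and a median of -0.48 (camera, adjusted p = 1.95e-19, n = 5 and 5; adjusted p = 6.47e-06 with an estimated correlation). Msmo1, a sterol C4 demethylation enzyme, stood at 629 ± 59 against 969 ± 96.9 CPM and Hmgcs1 at 1060 ± 102 against 1670 ± 318 CPM. In this list 6 passed adjusted over the list alone and 0 over all genes. SRF target and cytoskeleton genes rose as a list, with 20 of 29 above 0 and a median of 0.16 (adjusted p = 0.000121; adjusted p = 0.0408 with an estimated correlation). Tagln, the transgelin gene, stood at 22.3 ± 8.2 against 2.14 ± 1.91 CPM, and Flna, the filamin A gene, at 160 ± 25.5 against 108 ± 22.8 CPM, while 0 members passed over all genes. Ribosomal protein genes rose, with 25 of 29 above 0 and a median of 0.25 (adjusted p = 5.39e-07; adjusted p = 0.301 with an estimated correlation). All 3 calls held in each of the 10 fits that left out 1 library.

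Srf itself stood at 78.1 ± 10.6 (n = 5) against 92.3 ± 25.2 CPM (n = 5) at 6 h (log2 fold change -0.24 ± 0.27), and the difference between the 6 h and 1 h responses was -2.02 ± 0.39 (edgeR, adjusted p = 0.35). At 6 h edgeR called 0 genes (200 at an unadjusted p under 0.05), DESeq2 8 and voom with quality weights 79. Without aCSF replicate 3 edgeR called 1. Tfrc, the transferrin receptor, had the smallest adjusted p (96.5 ± 18.9 against 209 ± 36.1 CPM; edgeR, adjusted p = 0.076), and Stmn4 stood at -0.87 ± 0.23. Cx3cl1 (0.82 ± 0.21), Sema4a (1.14 ± 0.32) and Sdc4 (1.27 ± 0.37) were the highest by p. Pdgfra was at -0.08 ± 0.19, Mbp at 0.12 ± 0.23 and Fgfr2 at 0.69 ± 0.49. For the difference between the times edgeR called 0 (853 at an unadjusted p under 0.05), DESeq2 50 and voom with quality weights 10. Beside Srf, the smallest p belonged to Bag3 (-2.03 ± 0.44) and Stmn4 (-1.52 ± 0.33), and to Rpa3 (3.17 ± 0.79), Esrrg and Ginm1 in the other direction. The cholesterol response differed between the times (camera, adjusted p = 1.39e-07; adjusted p = 0.00158 with an estimated correlation), with 18 of 23 members lower at 6 h and a median of -0.60.

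**Figure D2:**
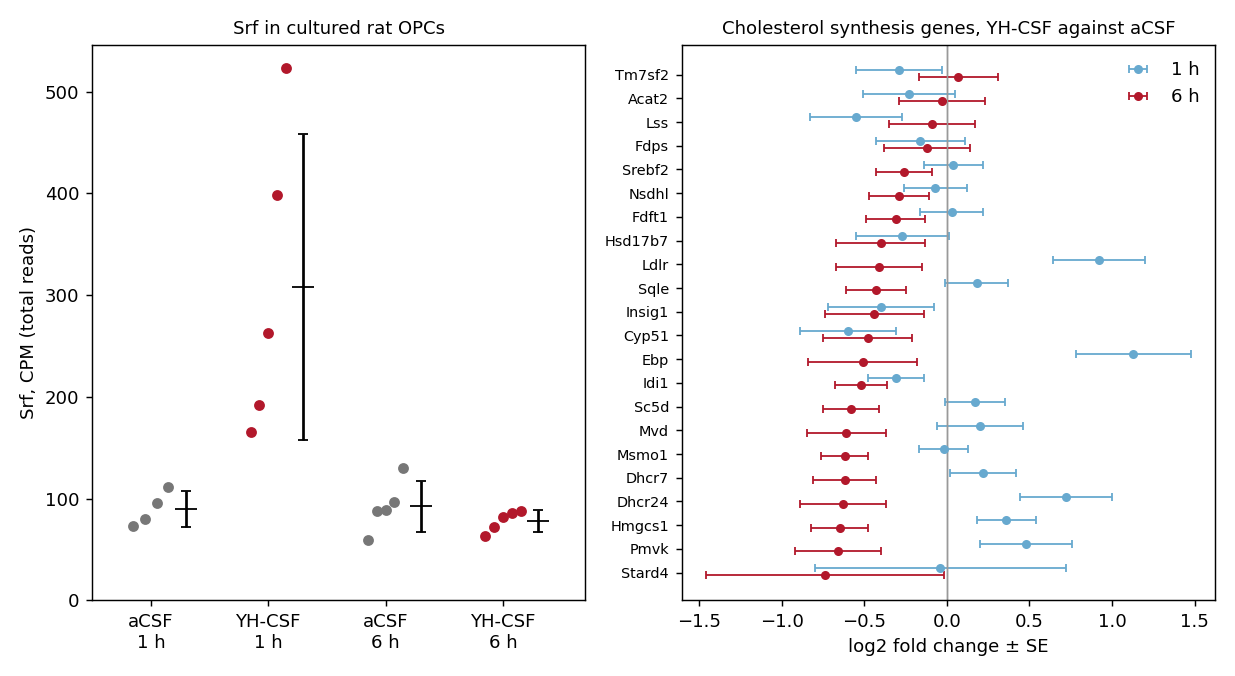
Left, Srf in total reads (CPM) of each culture library, with YH-CSF at 1 h at 165 to 523 and aCSF at 1 h at 72.5 to 111. Right, log2 fold change with SE of 22 of the 23 cholesterol synthesis genes, YH-CSF against aCSF, at 1 h in blue and at 6 h in red.

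Reads with T>C changes are meant to mark RNA made during the labelling. At 1 h FGF and ERK feedback genes rose as a list, with 8 of 9 above 0 and a median of 1.63 (camera, adjusted p = 0.00239; adjusted p = 0.0604 with an estimated correlation), a call lost with no low-count filter (0.0713), and so did SRF target and cytoskeleton genes, with 13 of 19 above 0 and a median of 1.03 (adjusted p = 0.00539; adjusted p = 0.0346 with an estimated correlation). Ccnd1 stood at 7620 ± 7910 (SD, n = 5) against 1710 ± 681 CPM (n = 4), Dusp6 at 951 ± 306 against 306 ± 38.3 CPM and Tpm1, a tropomyosin gene, at 4240 ± 6880 against 215 ± 212 CPM. In each of the lists 4 genes passed adjusted over the list alone and 0 over all genes. Srf stood at 500 ± 264 against 133 ± 80.6 T>C CPM (log2 fold change 1.91 ± 0.68; edgeR, adjusted p = 0.122). Glucocorticoid response genes fell as a list with a median of -0.48 (adjusted p = 0.00786; adjusted p = 0.0604 with an estimated correlation), with 6 of 9 members below 0. Tsc22d3, the glucocorticoid-induced leucine zipper gene, passed in this list adjusted over the list alone (1.58 ± 3.53 against 77.6 ± 59.5 CPM), and 0 did over all genes. This call was lost without YH-CSF replicates 3 and 5, which stood apart (adjusted p = 0.0765).

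Of single genes edgeR called 3 of 7479 in T>C reads at 1 h (1561 at an unadjusted p under 0.05), DESeq2 834 and voom with quality weights 0. Other splits of these libraries gave a median of 1357 genes at such a p. Usf2, a basic helix-loop-helix factor, rose to 1990 ± 2760 (n = 5) from 47.2 ± 19.1 CPM (n = 4) and Serinc3 to 608 ± 518 from 22.7 ± 19.9 CPM. Rwdd2b fell from 84 ± 48.4 CPM to 0 in all YH-CSF libraries, at least 31.5-fold lower over the group (edgeR, adjusted p = 0.0312 for each). The number of called genes hung on single libraries: it was 0 without aCSF replicate 1, 2 or 5 or YH-CSF replicate 5, 1 without aCSF replicate 3, 6 without YH-CSF replicate 3, 158 without YH-CSF replicate 4, 190 without YH-CSF replicate 2 and 512 without YH-CSF replicate 1. It was 0 with the 2 groups alone, 46 with no low-count filter and 16 with T>C counts scaled by total reads. Usf2 stayed called in 3 of the 9 fits that each left out 1 library (highest adjusted p 0.11, without aCSF replicate 1), Serinc3 in 4 and Rwdd2b in 5 (0.109 for each, without aCSF replicate 2). Without YH-CSF replicates 3 and 5 Usf2 was at 1.35 (0.438), and the calls of Serinc3 and Rwdd2b were lost too. Further genes by p were Elavl2 (-3.65 ± 0.81) and Ppp3ca (-3.46 ± 0.80). Pdgfra was at 0.02 ± 0.42 and Mbp at 0.79 ± 1.00, and Fgfr2 had T>C counts in 1 of the 9 libraries (16 counts, YH-CSF replicate 5), its counts in the culture being multiples of 16 throughout.

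At 6 h cholesterol synthesis genes fell in T>C reads too, with 23 of 23 members below 0 and a median of -0.54 (camera, adjusted p = 3e-07, n = 5 and 5; adjusted p = 0.000314 with an estimated correlation). Single genes gave 0 calls by edgeR (36 at an unadjusted p under 0.05), 1 by DESeq2 and 8 by voom with quality weights. Tagln stood at 34.3 ± 14.5 against 0.217 ± 0.485 CPM and Alas1, the first enzyme of haem synthesis, at 52.3 ± 15 against 7.39 ± 3.6 CPM (edgeR, adjusted p = 1 for each). Reep6 had 0 counts in all aCSF libraries (at least 18.8-fold higher over the group), and Tom1l1 (-4.65 ± 1.57) and Adcy9 (-5.05 ± 1.74) were the lowest by p. Srf was at -0.66 ± 0.60, Pdgfra at -0.09 ± 0.40, Mbp at 0.22 ± 0.92 and Fgfr2 at 1.77 ± 1.58. For the difference between the times edgeR called 0 (932 at an unadjusted p under 0.05), DESeq2 117 and voom with quality weights 0, and edgeR 12 without YH-CSF 1 h replicate 1. Serinc3, Usf2 and Ndel1 were lowest by p there, and Rwdd2b, Tmem9 and Ptgfrn highest (smallest adjusted p by edgeR 0.253). The cholesterol response differed between the times (camera, adjusted p = 0.00209; adjusted p = 0.0139 with an estimated correlation), with 18 of 23 members lower at 6 h and a median of -1.09, a call lost with no low-count filter (0.261).

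The share of reads with T>C changes holds new RNA and a background that was not measured, since no library without s4U was used here. At 1 h it was 2.73 ± 0.646% (n = 5) with YH-CSF and 3.47 ± 0.289% (n = 4) with aCSF (two-sided exact permutation test, p = 0.0794, adjusted p = 0.116), and at 6 h 12.1 ± 0.731% and 12.9 ± 0.426% (exact p = 0.0714, adjusted p = 0.116). For Srf the share was 5.79 ± 4.42% against 5.36 ± 3.06% at 1 h (exact p = 0.873) and 13.3 ± 4.39% against 18.7 ± 3.1% at 6 h (exact p = 0.0873). None of these 4 differences passed.

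Sorted nuclei were compared first by cell type. All OPC libraries had 18 cycles of preamplification and all OL libraries 16, so cell type and amplification cannot be told apart in this contrast. In OPC nuclei (n = 8) against OL nuclei (n = 7) all 19 OPC genes were higher, with a median log2 fold change of 4.32 (camera, adjusted p = 6.3e-28; adjusted p = 0.0258 with an estimated correlation). Pdgfra stood at 839 ± 161 against 23.4 ± 24.1 CPM and Gpr17, a receptor of committed precursors, at 825 ± 240 against 15.8 ± 22.6 CPM. Of 24 myelin genes 22 fell, with a median of -2.49 (adjusted p = 5.41e-26; adjusted p = 0.0258 with an estimated correlation). Mbp stood at 772 ± 182 against 3520 ± 565 CPM and Mog at 183 ± 73.1 against 1170 ± 222 CPM. The FGF receptors parted: Fgfr1 (91.7 ± 19.1 against 17.7 ± 3.16 CPM) and Fgfr3 (33.8 ± 19.4 against 6.27 ± 2.79 CPM) rose in OPCs, and Fgfr2 fell (306 ± 46.5 against 1240 ± 230 CPM). Fgfr3 is also a member of the astrocyte list, which was higher in the OPC nuclei too. Whether astrocyte nuclei were among the sorted ones was not tested. FGF and ERK feedback genes were higher in OPCs, 11 of 15 over all genes and 13 adjusted over the list alone, with a median of 2.59 (adjusted p = 1.35e-08; adjusted p = 0.0116 with an estimated correlation), such as Spry4 (76.8 ± 27.2 against 3.39 ± 3.48 CPM) and Etv5 (218 ± 64.9 against 26 ± 14.8 CPM).

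Genes of committed oligodendrocyte precursors were higher in OPC nuclei in 10 of 14 cases and lower in 2 (camera, adjusted p = 0.000113; adjusted p = 0.115 with an estimated correlation): Itpr2 was at 3.23 ± 0.21 and Enpp6 at -2.28 ± 0.23. Astrocyte genes were also higher in the OPC nuclei, 11 of 15 with a median of 1.46 (adjusted p = 1.76e-07; adjusted p = 0.0272 with an estimated correlation), among them Gpc5 (1850 ± 708 against 162 ± 113 CPM) and Slc1a2, the glutamate transporter of astrocytes (643 ± 185 against 155 ± 40.1 CPM). In OL nuclei the glucocorticoid response genes stood higher, with 7 of 17 called (adjusted p = 0.00163; adjusted p = 0.413 with an estimated correlation), for example Tsc22d3 (47.5 ± 27.5 CPM in OPCs, 249 ± 58.9 in OLs). The largest folds were those of Pcdhgc3 (145 ± 125 CPM in OPCs, 0 in all OL libraries, at least 3950-fold higher over the group), Ptk7, Ednra, Slc5a7, Fzd9, F2r and Dll3 for OPCs and of Cdr2, Clca4a, Depdc7, Asphd1, Tmprss12, Anln, Prr5l and Cdk18 for OLs, with Prr5l at 266 ± 50 against 3090 ± 844 CPM. In all 5040 of 21749 genes were called, 2995 higher and 2045 lower in OPCs (edgeR). Srf was at -0.59 ± 0.39 (adjusted p = 0.334).

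The age comparison asks how the lineage of the aged hippocampus differs from the young. In aged OL nuclei (n = 3) against young (n = 4) genes of complement and the acute phase rose: C4b, a complement component, to 586 ± 304 from 15.1 ± 12.3 CPM (edgeR, adjusted p = 0.0238) and Serpina3n, a protease inhibitor, to 47.2 ± 4.38 from 7.79 ± 4.65 CPM (adjusted p = 0.0304). Their NF-kB and acute phase list rose with 8 of 11 above 0, 2 called over all genes, 4 adjusted over the list alone and a median of 0.32 (camera, adjusted p = 0.000767; adjusted p = 0.516 with an estimated correlation). Further members were Socs3, an inhibitor of cytokine signalling (4.27 ± 1.62 against 0.0539 ± 0.0661 CPM), and Stat3 (138 ± 2.82 against 78.8 ± 16.3 CPM). Called genes outside this list include Cdh8, a cadherin (317 ± 142 against 42.5 ± 12.3 CPM; adjusted p = 0.00626), Unc5d, a netrin receptor (183 ± 43.9 against 39.8 ± 5.53 CPM; adjusted p = 0.00404), and Bdkrb2, a bradykinin receptor (log2 fold change 2.66 ± 0.29). Clic5 (2.75 ± 0.31), Ogdhl (2.43 ± 0.33) and Eya4 (2.31 ± 0.31) rose, and Sytl5 (-2.09 ± 0.30) and the phosphatase gene Ptpn13 (-1.44 ± 0.21) fell.

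**Figure D3:**
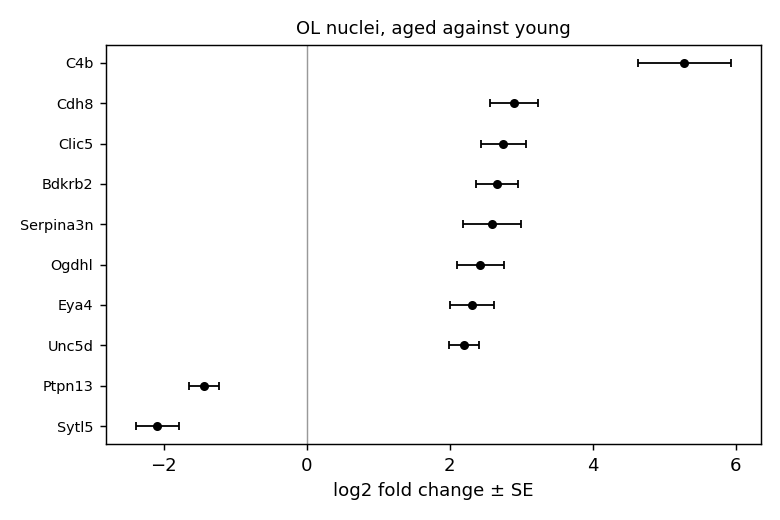
Log2 fold change with SE of 10 named genes in OL nuclei, aged (n = 3) against young (n = 4), from C4b at 5.28 to Sytl5 at -2.09.

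In aged OL nuclei edgeR called 29 of 18407 genes, 23 higher and 6 lower (1522 at an unadjusted p under 0.05), DESeq2 231 and voom with quality weights 214. Without 1 library the count was 20 without young replicate 1, 14 without young replicate 2, 33 without young replicate 3, 10 without young replicate 4, 24 without aged replicate 1, 10 without aged replicate 2 and 10 without aged replicate 3. Cdh8, Clic5, Bdkrb2 and Unc5d stayed called in all 7 of these fits. C4b was lost without young replicate 1 (0.077), 2 (0.0542) or 4 (0.11) or aged replicate 2 (0.155) or 3 (0.104). Serpina3n was lost in 5 of the 7 (highest adjusted p 0.217), Ogdhl in 3 (0.11), Eya4 in 3 (0.11), Sytl5 in 4 (0.122) and Ptpn13 in 6 (0.122). The count was 453 with no low-count filter. The libraries of this experiment were parted in 2 by the sign of the first component of their expression after the group means were removed (28.9% of the variance left). The parts also differed in genes detected, 22621 to 26932 in 6 libraries (2 young, 4 aged) and 17527 to 21806 in 9 (6 young, 3 aged). The split was drawn from the same expression values, so it is no independent measure of a batch. With this split as a term edgeR called 37, 28 of them among the 29.

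Genes of cholesterol synthesis fell with age in both cell types. In OL nuclei 20 of 24 members were below 0 with a median of -0.39 (camera, adjusted p = 3.69e-05; adjusted p = 0.516 with an estimated correlation), and 4 passed adjusted over the list alone, 0 over all genes, such as Cyp51 (19.5 ± 5.39 against 47.3 ± 10.8 CPM). In OPC nuclei (n = 4 and 4) 21 of 24 were below 0 with a median of -0.52 (adjusted p = 5.42e-06; adjusted p = 0.226 with an estimated correlation), such as Msmo1 (41.6 ± 16.6 against 80.9 ± 17.4 CPM). Both calls held in every fit that left out 1 library. Myelin genes fell in aged OPC nuclei, with 19 of 24 below 0 and a median of -0.37 (adjusted p = 5.42e-06; adjusted p = 0.372 with an estimated correlation), and Mal, a myelin proteolipid, passed adjusted over the list alone (113 ± 29 against 273 ± 102 CPM), 0 over all genes. Interferon and antigen presentation genes rose in aged OPC nuclei, with 17 of 22 above 0 and a median of 0.36 (adjusted p = 0.00168; adjusted p = 0.232 with an estimated correlation). Beside this, microglia genes rose too, with 11 of 15 above 0 and a median of 0.45 (adjusted p = 0.00168; adjusted p = 0.232 with an estimated correlation), a call lost without young replicate 3 (0.0829) or with voom with quality weights (0.0616). Trem2, a receptor of microglia, stood at 2.63 ± 1.53 CPM in aged and 0 in all young OPC libraries. Mitochondrially encoded genes fell, with 10 of 10 below 0 and a median of -0.70 (adjusted p = 0.00475; adjusted p = 0.433 with an estimated correlation), a call lost without young replicate 2 (0.11) or aged replicate 3 (0.0511).

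Over single genes of aged OPC nuclei edgeR called 0 of 17926 (729 at an unadjusted p under 0.05), DESeq2 203 and voom with quality weights 0. Without young replicate 1 or 4 or aged replicate 1 edgeR called 1. C4b stood at 153 ± 94 against 14.5 ± 4.62 CPM (edgeR, adjusted p = 0.129), Plce1, a phospholipase C, at 337 ± 40.4 against 134 ± 15.6 CPM (adjusted p = 0.129) and Cdh8 at 58.3 ± 26.6 against 13.4 ± 1.83 CPM. Dnajb9 (-1.86 ± 0.39), Synpr (-1.32 ± 0.29) and Dhx29 (-1.29 ± 0.29) were lowest by p. Pdgfra was at -0.17 ± 0.22, Fgfr1 at -0.06 ± 0.23, Fgfr2 at -0.09 ± 0.22 and Srf at -0.51 ± 0.74 in OPC nuclei, and Srf at -0.46 ± 0.37 and Mbp at 0.29 ± 0.21 in OL nuclei. The age effect itself was compared between the cell types: edgeR called 0 genes (742 at an unadjusted p under 0.05; smallest adjusted p 0.923), DESeq2 68 and voom with quality weights 0. Without OPC young replicate 1 (which stood apart) or 4 or OPC aged replicate 2 or 3 edgeR called 1. Named genes of smallest p there were Ccdc34os, Dclk3 and Piezo2 (1.89 ± 0.44), higher, and Abcc4 (-2.29 ± 0.54) and Syne2 (-1.28 ± 0.33), lower.

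Nuclei after a single injection address which cells answer CSF within hours. In OL nuclei glucocorticoid response genes rose as a list 1 h after YM-CSF (n = 4) against aCSF (n = 4), with 14 of 17 above 0 and a median of 0.51 (camera, adjusted p = 8.18e-09; adjusted p = 0.162 with an estimated correlation). Errfi1, a feedback inhibitor of EGF receptors, stood at 217 ± 44.6 against 134 ± 4.91 CPM, Zbtb16 at 1300 ± 148 against 909 ± 117 CPM and Fkbp5, a co-chaperone of the glucocorticoid receptor, at 273 ± 58.6 against 185 ± 42.1 CPM. Adjusted over the list alone 10 genes passed, 0 over all genes. At 6 h the list rose again, with 15 of 17 above 0 and a median of 0.25 (adjusted p = 2.27e-11; adjusted p = 0.0719 with an estimated correlation), and 2 genes, Errfi1 and Zbtb16, passed adjusted over the list alone, 0 over all genes. List levels were 6.10 ± 0.30 against 5.57 ± 0.08 log2 CPM at 1 h and 6.88 ± 0.05 against 6.64 ± 0.15 at 6 h (two-sided exact permutation tests, p = 0.0286 each, the smallest these groups allow; adjusted p = 0.315 and 0.629). Both calls held in every fit that left out 1 library. At 1 h the aCSF replicates 1 and 2 stood apart from the others.

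**Figure D4:**
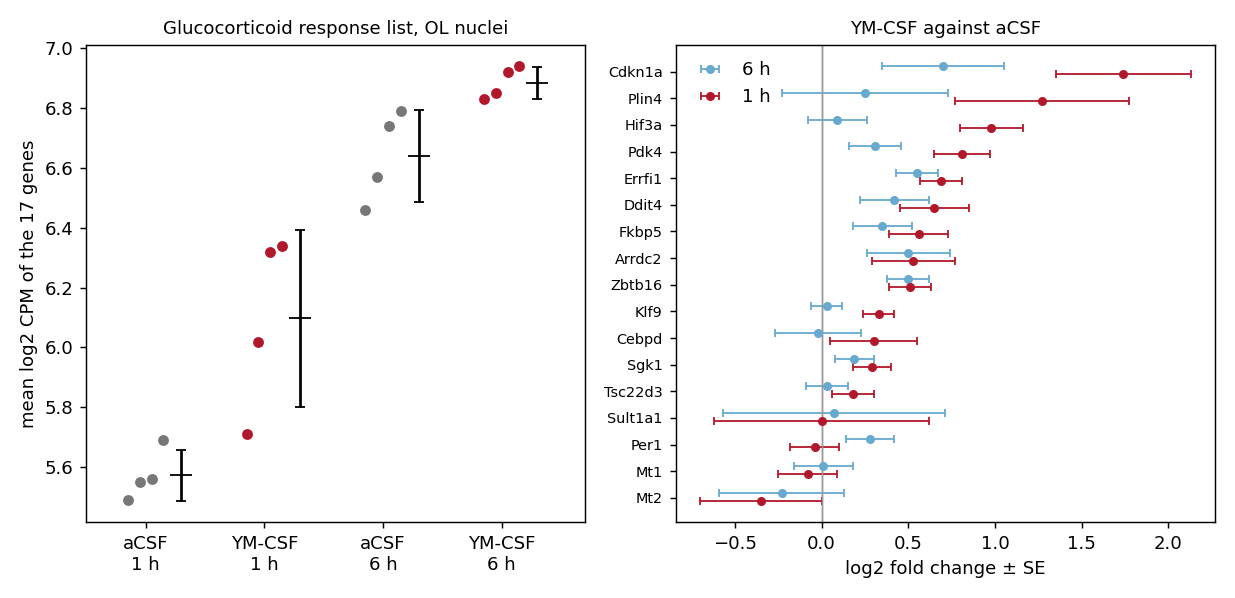
Left, mean log2 CPM of the glucocorticoid response genes in each OL library (1 h: aCSF 5.49 to 5.69, YM-CSF 5.71 to 6.34; 6 h: aCSF 6.46 to 6.79, YM-CSF 6.83 to 6.94). Right, log2 fold change with SE of the 17 genes, YM-CSF against aCSF, at 1 h in red and at 6 h in blue.

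At 1 h other groups moved beside these genes in the OL nuclei. Mitochondrially encoded genes fell, with 10 of 10 below 0 and a median of -0.63 (camera, adjusted p = 0.000103; adjusted p = 0.528 with an estimated correlation), such as mt-Cytb (15.4 ± 4.97 against 27 ± 8.9 CPM). Ribosomal protein genes fell, with 30 of 34 below 0 (adjusted p = 7.23e-05; adjusted p = 0.347 with an estimated correlation). Both calls were lost without aCSF replicates 1 and 2 (adjusted p = 0.259 each). At 6 h ribosomal protein genes fell again (adjusted p = 0.00168; adjusted p = 0.498 with an estimated correlation), a call lost without aCSF replicate 2 (0.0614) or YM-CSF replicate 4 (0.0818). Neuron genes fell at 6 h (adjusted p = 0.000654; adjusted p = 0.498 with an estimated correlation), a call lost without aCSF replicate 2 (0.152).

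In OL nuclei at 1 h 1770 single genes had an unadjusted p under 0.05, and other splits of these libraries gave a median of 1342. Of 16285 genes DESeq2 called 160, voom with quality weights 0 and edgeR 0. Without aCSF replicate 2 the count was 2, without aCSF replicate 3 it was 1, without aCSF replicate 4 it was 42, without YM-CSF replicate 1 it was 8, without YM-CSF replicate 4 it was 3, and without aCSF replicates 1 and 2 it was 5. With no low-count filter it was 19. Tubb3, a neuronal tubulin, stood at 134 ± 14.2 against 93.6 ± 3.79 CPM and Daam2 at 1210 ± 80.7 against 894 ± 19.3 CPM (edgeR, adjusted p = 0.0642 each), Bcl2l1, an inhibitor of apoptosis, at 1290 ± 139 against 936 ± 64 CPM and Sec11c at 189 ± 10 against 276 ± 38.1 CPM. Atp5j was at -0.65 ± 0.13 and Gucy1a1 at -1.87 ± 0.39. At 6 h edgeR called 0 (347 at an unadjusted p under 0.05), DESeq2 26 and voom with quality weights 13, and edgeR 3 without aCSF replicate 3. Tma16 (1.47 ± 0.27), Otud7a (0.37 ± 0.08) and Mxd4 (0.46 ± 0.10) were highest by p, and Eml1 (-0.39 ± 0.11), Map6d1 (-0.28 ± 0.08) and the low-count Hist2h2aa1 lowest. For the difference between the times edgeR called 0 (589 at an unadjusted p under 0.05), DESeq2 3 and voom with quality weights 0, 2 by edgeR without aCSF 1 h replicate 1 and 1 without both aCSF libraries that stood apart. Among named genes its smallest p belonged to Pcdhgb1, Sec11c and Tarsl2, higher, and Tmem74b, Tubb3 and Sstr3, lower. Srf was at -0.36 ± 0.37 at 1 h and 0.08 ± 0.38 at 6 h, and Mbp at 0.04 ± 0.07 and 0.06 ± 0.07.

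In OPC nuclei after the injection no list was called at 1 h or 6 h. Srf stood at 1.29 ± 1.05 (n = 4) against 3.74 ± 5.57 CPM (n = 4) at 1 h, with log2 fold changes of -1.53 ± 1.91 at 1 h and 1.49 ± 1.91 at 6 h, each SE being larger than the change of Srf in the culture. At 1 h edgeR called 0 of 18155 genes (813 at an unadjusted p under 0.05), DESeq2 96 and voom with quality weights 0, and edgeR 1 without aCSF replicate 1. At 6 h edgeR called 0 (893), DESeq2 125 and voom 0, and for the difference between the times 0 (743), 120 and 0. At 1 h Cd68 had 0 counts in all aCSF libraries (at least 102-fold higher over the group), Taf9 (at least 211-fold lower) and Rgs5 (at least 79.4-fold lower) had 0 in all YM-CSF libraries, and Emc3 was at -1.05 ± 0.24 (edgeR, adjusted p = 1 each). At 6 h Rbm39, a splicing factor, stood at 782 ± 113 against 512 ± 40.3 CPM (edgeR, adjusted p = 0.605), Nup88 at 1.34 ± 0.28 and Dmxl1 at 0.69 ± 0.15, and Tyw1 (-1.49 ± 0.28), Faxc (-1.83 ± 0.39) and Plekhn1 (0 in all YM-CSF libraries, at least 77.7-fold lower over the group) were lowest by p. For the difference between the times Gadd45b, Rgs5 and Taf9 were highest by p and Chn1os3, Tyw1 and Kcnrg lowest. Pdgfra was at 0.14 ± 0.15 at 1 h and -0.28 ± 0.15 at 6 h, and Fgfr1 at -0.09 ± 0.28 and -0.49 ± 0.28.

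At 16 h OPC nuclei address whether young and aged CSF differ in effect. Several lists called here hold genes of cell types other than OPCs. Whether other cells or their RNA were among the sorted nuclei was not tested. Endothelial and pericyte genes rose with YM-CSF (n = 4) against aCSF (n = 3), with 16 of 16 above 0 and a median of 1.87 (camera, adjusted p = 2.05e-09; adjusted p = 0.674 with an estimated correlation), such as Flt1, a VEGF receptor (260 ± 59.6 against 33.2 ± 23 CPM), while 0 members passed over the list alone or over all genes. OPC genes fell beside them, with 17 of 19 below 0 and a median of -0.53 (adjusted p = 0.00118; adjusted p = 0.674 with an estimated correlation). Olig1, a lineage transcription factor, stood at 755 ± 425 against 1620 ± 172 CPM and Pdgfra at 771 ± 362 against 1190 ± 132 CPM. Pdgfra ran from 356 to 1170 CPM over the YM-CSF libraries and from 1040 to 1290 CPM over the aCSF libraries. Both calls held in all 7 fits that left out 1 library. Myelin genes rose, with 18 of 24 above 0 and a median of 0.35 (adjusted p = 0.00433; adjusted p = 0.674 with an estimated correlation), a call lost without YM-CSF replicate 1 (0.118) or aCSF replicate 3 (0.119). With AM-CSF (n = 4) choroid plexus genes rose, with 13 of 14 above 0 and a median of 2.36 (adjusted p = 1.81e-09; adjusted p = 0.544 with an estimated correlation), such as Ttr, the transthyretin gene (424 ± 251 against 22.4 ± 12.5 CPM). Endothelial genes rose there as well, with 15 of 16 above 0 and a median of 1.88 (adjusted p = 0.000857; adjusted p = 0.658 with an estimated correlation), a call lost without AM-CSF replicate 2 (0.105).

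Between YM-CSF and AM-CSF at 16 h choroid plexus genes were lower with YM-CSF (camera, adjusted p = 7.97e-05; adjusted p = 0.924 with an estimated correlation), a call lost without YM-CSF replicate 3 (0.0791), and astrocyte genes higher (adjusted p = 0.000174; adjusted p = 0.924 with an estimated correlation), a call lost without AM-CSF replicate 3 (0.273) or with voom with quality weights (0.104). YM-CSF replicate 4 and AM-CSF replicate 4 stood apart from the other libraries. EdgeR called 0 of 19723 genes in each of the 3 contrasts, with 935 at an unadjusted p under 0.05 for YM-CSF against aCSF (DESeq2 59), 571 for AM-CSF against aCSF (DESeq2 37) and 518 for YM-CSF against AM-CSF (DESeq2 35), and voom with quality weights called 0 in each. By smallest p Adipor2, an adiponectin receptor (185 ± 65.6 against 74.1 ± 5.41 CPM), and Akap2 (1.89 ± 0.41) were higher with YM-CSF, and Sprn (-1.54 ± 0.33), Basp1 (-0.90 ± 0.20) and Slc22a17 (-0.82 ± 0.20) lower. Tmem252 had 0 counts in all aCSF libraries (at least 76-fold higher with YM-CSF and 112-fold with AM-CSF over the group). With AM-CSF Emsy (0.86 ± 0.20) was higher and Ctsl, a lysosomal protease (62.9 ± 3.6 against 108 ± 5.75 CPM), Slc38a3 (-0.71 ± 0.19) and Tmem9 (-0.95 ± 0.26) lower. Drg1 (0.89 ± 0.24), Pcdhga2 (0 in all AM-CSF libraries, at least 648-fold higher over the group) and Tmprss12 were higher with YM-CSF than with AM-CSF, and Nsg2 (-1.16 ± 0.33), Tuba8 and Mov10l1 lower. Srf was at -0.54 ± 0.97 with YM-CSF and -0.34 ± 0.97 with AM-CSF.

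The genes of one experiment were also tested as lists in another. Of the 200 genes of smallest p that were higher in aged OL nuclei 197 were tested in OL nuclei after injection, and they rose with YM-CSF at 1 h, with 132 above 0 (camera, adjusted p = 2.41e-05; adjusted p = 0.0202 with an estimated correlation), and at 6 h, with 124 above 0 (adjusted p = 2.41e-05; adjusted p = 0.0202 with an estimated correlation). Genes lower in aged OL nuclei fell at 1 h (adjusted p = 0.000195; adjusted p = 0.286 with an estimated correlation) and at 6 h (adjusted p = 1.47e-06; adjusted p = 0.207 with an estimated correlation). With an estimated correlation the rise held in 5 of 8 fits that left out 1 library at 1 h (lost without aCSF replicate 2, 0.0857, or YM-CSF replicate 3, 0.0635, or 4, 0.0928) and in 6 of 8 at 6 h (lost without aCSF replicate 1, 0.0535, or YM-CSF replicate 4, 0.0585). At the preset correlation the fall at 1 h was lost without aCSF replicate 2 (0.121) or YM-CSF replicate 4 (0.136). Lists of the called genes alone gave 0 of 4 calls. The contrast of aged and young OPC nuclei had 0 called genes and 729 at an unadjusted p under 0.05, where 896 were expected by chance. Lists drawn from it rank genes by p and are thus not shown to hold genes that differ with age. For the 200 genes of smallest p in aged OPC nuclei 3 of 10 tests in the OPC nuclei of the injections were called and 0 with an estimated correlation (smallest adjusted p 0.216). For the 100 genes of smallest p 2 of 10 were called, both for genes lower in aged OPC nuclei: they were lower with AM-CSF than with aCSF at 16 h (adjusted p = 0.0134; adjusted p = 0.0356 with an estimated correlation) and higher with YM-CSF than with AM-CSF (adjusted p = 0.00274; adjusted p = 0.0254 with an estimated correlation), 2 contrasts that share the AM-CSF libraries. The first was lost without aCSF replicate 2 (0.19) or AM-CSF replicate 2 (0.0755), and the second held in all 8 fits that left out 1 library. With an estimated correlation they held in 3 of 7 and 4 of 8 such fits (highest adjusted p 0.157, without aCSF replicate 2, and 0.159, without YM-CSF replicate 4). Lists of the genes of smallest p in the culture gave 0 calls of 32 in the nuclei and the hippocampus for 100 or 200 genes from total or T>C reads. At 6 h the culture had 200 genes at an unadjusted p under 0.05 in total reads (508 expected by chance) and 36 in T>C reads (374 expected). The 6 h lists thus hold genes with little evidence of a response, and their lack of calls cannot decide whether the culture response is shared. The list sizes of 100 and 200 genes were chosen after the data were seen.

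**Figure D5:**
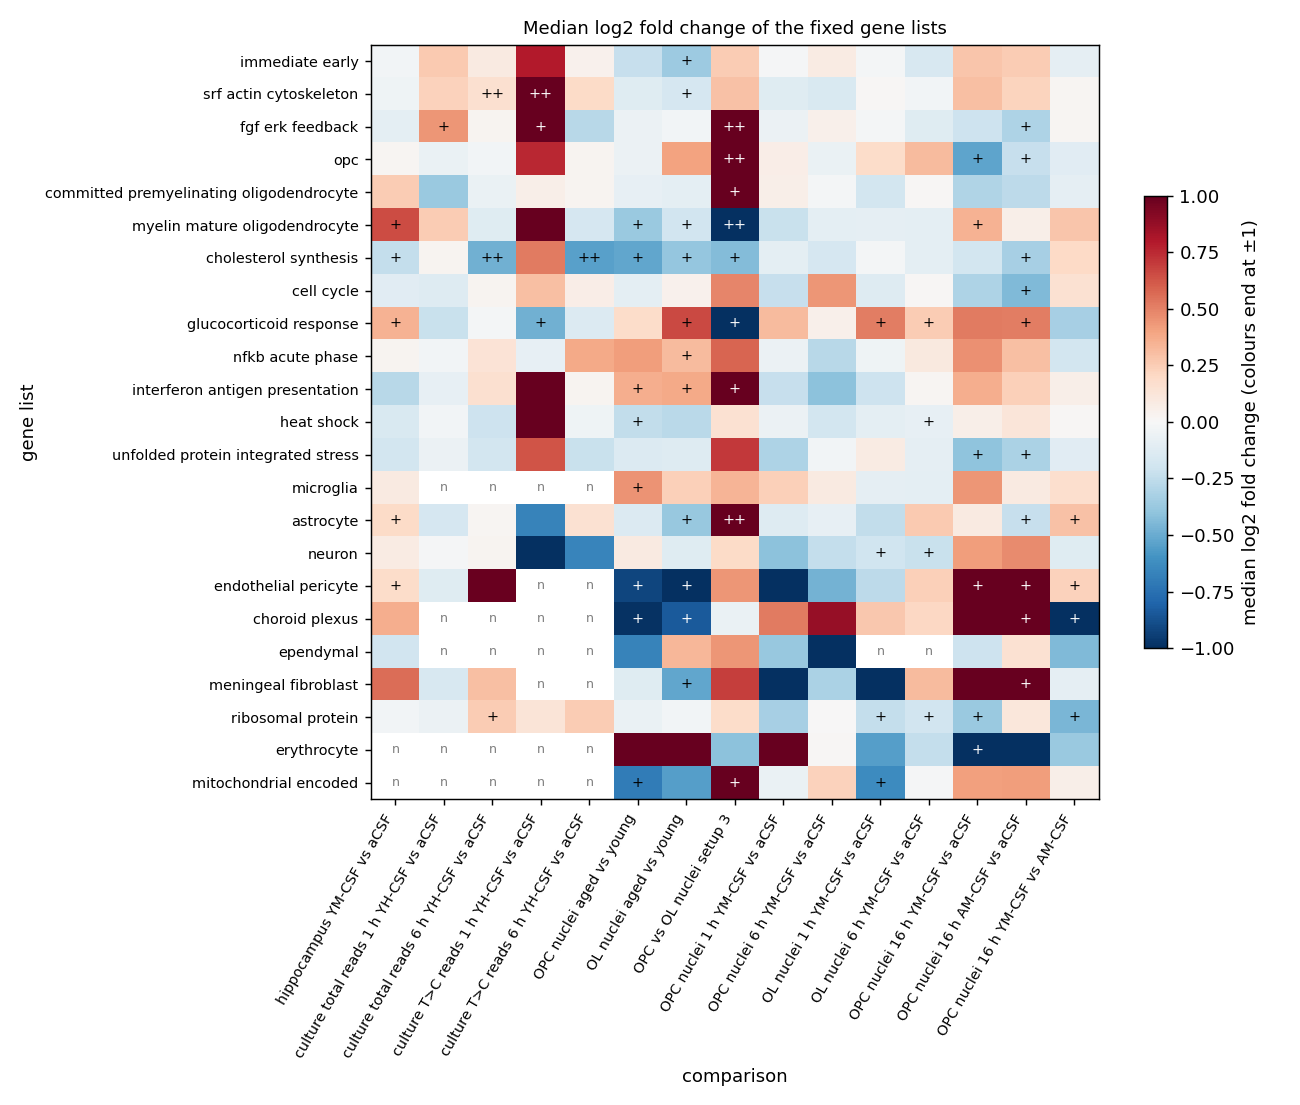
Median log2 fold change of each gene list (vertical axis) in each contrast (horizontal axis), with colours that end at 1 and -1. A plus marks a camera call, a double plus a call that also holds with an estimated correlation, and n a list that was not tested.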

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

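The tests of choroid plexus tissue, of the neuron share, of the libraries that stand apart and of RNA outside the nuclei were chosen after the result was seen, while those of depth and of other splits of the samples were chosen before. Single libraries far from the others of their group came first. Chance flags about 1 in 20 groups, and of 104 groups tested 8 held such a library where 5.2 were expected, not far above chance.

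In the culture aCSF 1 h replicate 2 had a total of 8.48 M reads (others 11.6 to 12.2) and YH-CSF 1 h replicate 2 one of 7.73 M (9.63 to 10.1). OL nuclei of aCSF 1 h replicate 4 had 16.1 M reads (8.43 to 9.64). Detected genes were 16537 in OPC nuclei of YM-CSF 16 h replicate 4 (21628 to 22214) and 16915 in OPC nuclei of YM-CSF 1 h replicate 1 (19852 to 20340). Srf was at 0 CPM in OPC nuclei of aCSF 6 h replicate 4 (1.55 to 1.82). Cholesterol synthesis genes had a level of 3.49 log2 CPM in OPC nuclei of young replicate 1 (4.45 to 4.62) and of 4.39 in OL nuclei of young replicate 1 (4.90 to 4.98).

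Responses that differed between 2 times or 2 cell types, by a test of the difference itself, came next. In the culture the FGF and ERK feedback genes were lower at 6 h than at 1 h relative to aCSF, in total reads with 8 of 10 genes lower and a median of -0.47 (camera, adjusted p = 0.0317; adjusted p = 0.428 with an estimated correlation), called in 12 of 19 fits that each left out 1 library (highest adjusted p 0.0956, without aCSF 1 h replicate 5). In T>C reads 7 of 9 were lower with a median of -1.94 (adjusted p = 0.00726; adjusted p = 0.106 with an estimated correlation), a call lost with no low-count filter (0.0818). The cholesterol response differed in total reads (adjusted p = 1.39e-07) and in T>C reads (0.00209, lost with no low-count filter, 0.261). Genes of the unfolded protein and integrated stress response were lower in T>C reads, 10 of 15 with a median of -0.58 (adjusted p = 0.0478; adjusted p = 0.106 with an estimated correlation), called in 11 of 19 such fits (highest 0.156, without aCSF 1 h replicate 1) and lost with no low-count filter (0.315), without the libraries that stand apart (0.157), with counts divided by their common factor (0.055), RLE size factors (0.052), the replicate number as a block (0.0513) or total-read scaling (0.0502).

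The age effect differed between OPC and OL nuclei for 3 lists, each at an adjusted p of 0.0452 by camera. Lower or higher here is the age effect in OPCs less that in OLs. Glucocorticoid response genes were lower in OPCs with 12 of 17 below 0 and a median of -0.73 (adjusted p = 0.808 with an estimated correlation), called in 6 of 15 fits (highest adjusted p 0.324, without OPC young replicate 4). NF-kB and acute phase genes were lower with 9 of 14 below 0 and a median of -0.60 (adjusted p = 0.311 with an estimated correlation), called in 6 of 15 (0.179, without OL aged replicate 3). Microglia genes were higher with 11 of 15 above 0 and a median of 0.55 (adjusted p = 0.555 with an estimated correlation), called in 7 of 15 (0.205, without OPC young replicate 3). With the replicate number as a block, which sets OPC and OL libraries of equal age and number together, the microglia call was lost (camera, adjusted p = 0.261), and the glucocorticoid (0.00174) and NF-kB (0.0331) calls were kept. The glucocorticoid call was also lost without the library that stands apart (0.142), with voom with quality weights (0.151) and with RLE size factors (0.0521), the NF-kB call without that library (0.0613) and with no low-count filter (0.0896), and the microglia call without it (0.142), with voom (0.136) and with no filter (0.118). With the 2-part split of these libraries as a term no call of the 3 was kept (adjusted p = 0.154, 0.0853 and 0.154).

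In OL nuclei the response to YM-CSF differed between 6 h and 1 h for 4 lists, each at an adjusted p of 0.0328 by camera and 0.97 with an estimated correlation. Relative to aCSF, glucocorticoid response genes were lower at 6 h than at 1 h with a median of -0.15 (13 of 17), though the list was above aCSF at both times. Astrocyte (0.76, 13 of 15), meningeal (1.17, 4 of 4) and mitochondrially encoded genes (0.56, 9 of 10) were higher at 6 h relative to aCSF. The 4 lists were called in 6, 7, 7 and 8 of 16 fits that each left out 1 library, with highest adjusted p of 0.375 (without aCSF 6 h replicate 3), 0.888 (YM-CSF 6 h replicate 3), 0.205 (aCSF 6 h replicate 3) and 0.28 (aCSF 1 h replicate 1). Without aCSF 1 h replicates 1 and 2 the glucocorticoid (0.318), astrocyte (0.27) and mitochondrial (0.766) calls were lost, and with voom with quality weights the astrocyte call (0.104).

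The higher myelin genes of the hippocampus were weighed first. Within groups their level did not follow that of choroid plexus genes (r = -0.19, upper 95% bound 0.38, rho = -0.17, permutation p = 0.5, r = -0.32 without the 2 farthest libraries), which argues against more tissue that carries choroid plexus, while neighbouring white matter holds the same myelin genes and was not tested apart. Against a lower neuron share, myelin rose by 0.64 more than the OPC list (exact permutation p = 0.012), and the neuron level itself was 0.10 higher. Without aCSF replicates 7 and 8 the difference was 0.71 (exact p = 0.024, 6 aCSF libraries left), which argues against these 2 as the cause. More myelin RNA per cell, more oligodendrocytes and uneven dissection of white matter may each give the pattern and stay open.

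The higher Srf of the culture at 1 h was weighed next. Without YH-CSF replicates 3 and 5, which had few genes detected, the log2 fold change went from 1.78 ± 0.30 to 1.21 ± 0.24 and the adjusted p from 0.0452 to 0.165, so that these 2 account for part of the size but not for the direction, and the call ended with a smaller change and fewer libraries. With all libraries thinned to 6.41 M reads it was 1.79 ± 0.30 (edgeR, adjusted p = 0.053). Random thinning keeps the share of Srf reads, so it could hardly move the fold change and cannot decide on depth. An effect of the plate position or of the pooled fluid on all wells alike stays open, since each time was 1 plate.

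The higher glucocorticoid response genes of OL nuclei at 1 h were weighed last. Without aCSF replicates 1 and 2 the difference was 0.48 (SE 0.16, exact permutation p = 0.13), against 0.53 with all libraries, with the lowest YM-CSF library at 5.71 and the highest aCSF library at 5.69. The list stayed called at camera's preset correlation (adjusted p = 1.62e-06), though it is not called with an estimated one even with all libraries (0.162), while the same step ended the mitochondrial and ribosomal calls (0.259 each). The difference less 2 of its SE stays above 0 but not above 0.25, the bound set first, which was lowered to 0 after the value was seen. The lowered bound was met, with only 2 aCSF libraries left. YM-CSF replicates 1 and 2 stayed in, though a split of replicates 1 and 2 of both fluids from the others gave 69 calls. Leaving out the 2 aCSF libraries alone thus cannot decide whether this structure gave the difference. Over 16 libraries the level went with that of mitochondrially encoded genes at r = -0.34 (rho = -0.30, permutation p = 0.19, r = -0.28 without the 2 farthest), and at 6 h both were higher with YM-CSF (glucocorticoid genes by 0.24, mitochondrial by 0.29). A change in RNA from outside the nuclei cannot be told apart from a response of the OLs, since r lies between the values that would decide. Stress of handling that differed between the groups could act on the same genes and was not tested.

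Other splits of the same libraries were also fitted, and the real split is counted among them. Chance could be excluded for OPC against OL nuclei, where 1 of 60 splits gave as many calls as the real 5040 (highest other 1659). It could not be excluded for aged against young OL nuclei, where 2 of 35 gave as many as 29. The highest other split there called 1589, many times the real count, which points to a structure of the samples. It parts young replicate 3 and aged replicates 2 and 3 from the rest, as the 2-part split of these libraries does. With that 2-part split as a term 37 were called, but it was drawn from the same expression values and gives no independent support. For culture total reads at 1 h, where Srf was the 1 called gene, 7 of 100 splits called as many as 1 gene (highest other 34). Chance could not be excluded for this count, which takes any gene, so that Srf itself was not tested by the splits. For T>C reads at 1 h 69 of 100 called as many as 3 (highest other 506), so that chance could not be excluded either, and the size of the highest again points to a structure of the samples. Counts of genes at an unadjusted p under 0.05 were compared over the splits too. The real count was reached in 5 of 100 for the hippocampus (median of the others 544), 9 of 100 for total reads at 1 h (591) and 6 of 35 for aged OL nuclei (453.5). It was reached in 16 of 100 for T>C reads at 1 h (1357) and 7 of 35 for OL nuclei at 1 h (1342). By the count of calls, where 0 genes were called all splits count as large. These were 100 of 100 for the hippocampus (highest other 135, which points to a structure of the samples that no label names and that was not tested), for total reads at 6 h (0) and between times (1), for T>C reads at 6 h (0) and between times (8), and for the difference between times in OPC nuclei (1) and OL nuclei (1). They were 60 of 60 for the age effect between cell types (2688, which largely follows the 2-part split of these libraries). They were 35 of 35 for aged OPC nuclei (6), OPC nuclei at 1 h (1) and 6 h (1), OL nuclei at 1 h (69, a split that parts aCSF and YM-CSF replicates 1 and 2 from the others) and 6 h (0), and OPC nuclei at 16 h for YM-CSF (2), AM-CSF (0) and YM-CSF against AM-CSF (1).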

How the results depend on the processing

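The fits without libraries that stand apart, those with the 2-part split of the age experiment, those with counts divided by their common factor and the lists of the 100 or 200 genes of smallest p and of called OL genes carried between experiments were chosen after the data were seen. For the 20 counts of called genes 361 alternatives were run, of which 279 stayed within 1.5 times the count and 82 moved. For the 81 called list tests 1092 of 1474 alternatives kept the call, 381 lost it with the same direction and 1 reversed. For named genes the direction held in all 2245 and the side of the threshold in 2111, with 132 weaker and 2 stronger. Among them 1940 of 2002 for OPC against OL and 99 of 130 for OL age kept both, and the rest were weaker. The 2 stronger ones are Srf between 6 h and 1 h in total reads.

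With DESeq2 the calls were 134 in the hippocampus, 74, 8 and 50 in culture total reads at 1 h, at 6 h and between times, 834, 1 and 117 in T>C reads, 203 in aged OPC nuclei, 231 in aged OL nuclei, 68 for the age effect between cell types, 96, 125 and 120 in OPC nuclei at 1 h, 6 h and between times, 160, 26 and 3 in OL nuclei, and 59, 37 and 35 at 16 h. The cause was not tested. With voom and quality weights they were 3, 79 and 10 in total reads, 0 and 8 in T>C reads at 1 h and 6 h, 214 in aged OL nuclei and 13 in OL nuclei at 6 h, and the cause was not tested. With no low-count filter 46 were called in T>C reads at 1 h, 2 in aged OPC nuclei, 453 in aged OL nuclei and 19 in OL nuclei at 1 h, with more genes tested. RLE size factors gave 0 in total reads at 1 h, the 2 groups alone 0 in total and in T>C reads at 1 h, and total-read scaling 16 in T>C reads at 1 h, and the cause was not tested. With counts divided by their common factor the same 1 and 3 genes were called in total and T>C reads at 1 h and 0 in the other culture contrasts.

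With the replicate number as a block 12 genes were called in the hippocampus, 0 in total and in T>C reads at 1 h, and 14 in aged OL nuclei. Between OPC and OL nuclei the block set libraries of equal age and number together, young ones included. It ended the microglia call of the age effect and no other list call there. By their correlations the numbers of groups other than the aged nuclei were not taken as pairs. Young OPC and OL libraries each correlated best with their own number (4 of 4, at 0.08 to 0.35), as did YM-CSF and AM-CSF with aCSF at 16 h (3 of 3 each, at 0.02 to 0.07), and in the other comparisons not every library did. Without the libraries that stand apart, thus with fewer samples, 0 were called in total reads at 1 h, 1 in aged OPC nuclei, 1 for the age effect between cell types, 5 in OL nuclei at 1 h and 1 between times. Of the 81 list calls 10 held with an estimated correlation. Fry called 19 of all 419 list tests, and not all of these are among the 81: it called the SRF target list in 4 contrasts and camera in 3. Of the age lists tested in the injections 0 of 3 OPC calls held with an estimated correlation at 200 genes and 2 of 2 at 100, and 2 of 4 OL calls at 200, with 0 calls for called OL genes alone. Planned tests of called culture genes and called aged OPC genes as lists were not run, since these lists were too small.

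Leaving out 1 library gave 0 to 1 calls in the hippocampus, 0 to 10 in total reads at 1 h, 0 to 1 at 6 h, 0 to 512 in T>C reads at 1 h, 0 to 12 between times, 0 to 1 in aged OPC nuclei, 10 to 33 in aged OL nuclei, 4234 to 5462 for OPC against OL, 0 to 1 for the age effect between cell types, 0 to 1 in OPC nuclei at 1 h, 0 to 42 in OL nuclei at 1 h, 0 to 3 at 6 h and 0 to 2 between times. It gave 0 in total reads between times, in T>C reads at 6 h, in OPC nuclei at 6 h and between times and in the 3 contrasts at 16 h. Heat shock genes in OL nuclei at 6 h turned upward without YM-CSF replicate 1 (adjusted p = 0.779, against 4.22e-05 to 0.779 over the 8 such fits), and the cause was not tested.

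Some settings moved the median log2 fold change of all genes by over 0.1. For T>C reads at 1 h it went from -0.077 to -0.558 with total-read scaling, 0.055 with RLE factors and -0.36 with the block. For T>C reads between times it went from 0.077 to 0.474, -0.043 and 0.392 in the same order, 0.268 with no filter, 0.29 with voom and -0.275 with DESeq2. It went from 0.006 to 0.138 with no filter and 0.135 with DESeq2 in aged OPC nuclei, from 0.036 to 0.164 and 0.184 in aged OL nuclei, and from 0.067 to -0.171 with voom, -0.254 with DESeq2 and -0.112 with the block for OPC against OL. In OPC nuclei at 6 h it was -0.138 with voom, and at 16 h -0.168 for YM-CSF and -0.064 for AM-CSF with the block. In simulated data 0% of planted 2-fold or 4-fold changes were called for T>C reads at 1 h and for YM-CSF at 16 h, and 2% of 2-fold changes in OPC nuclei at 6 h.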

Other observations

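In aged OL nuclei further lists passed at camera's preset correlation and 0 of the 11 called there passed with an estimated one (adjusted p = 0.516 to 0.587). Interferon and antigen presentation genes rose (14 of 20, adjusted p = 0.0213) and glucocorticoid response genes rose (12 of 17, 0.0134), with Hif3a and Plin4 passing adjusted over the list alone and 0 over all genes. Immediate early genes (23 of 30), SRF targets (22 of 35), myelin genes (17 of 24) and astrocyte genes (11 of 15) fell, at 0.0134 each. Endothelial (0.00473), choroid plexus (0.0109) and meningeal genes (0.029) fell as well. Each of these 9 calls was lost in at least 1 of 7 fits that left out 1 library, with a highest adjusted p of 0.164 for interferon genes (without aged replicate 1), 0.116 for glucocorticoid (young 2), 0.0743 for immediate early (young 4), 0.11 for SRF targets (young 4), 0.105 for myelin (aged 2), 0.11 for astrocyte (young 4), 0.0743 for endothelial (young 4), 0.0865 for choroid plexus (aged 1) and 0.4 for meningeal genes (aged 1). In aged OPC nuclei choroid plexus genes fell (10 of 11, adjusted p = 0.00136; 0.226 with an estimated correlation), as did heat shock (12 of 14, 0.027; 0.372) and endothelial genes (13 of 16, 0.0293; 0.433), the last 2 lost in 5 and 3 of 8 such fits.

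Between OPC and OL nuclei mitochondrially encoded genes were higher in OPCs (10 of 10, adjusted p = 0.00796; 0.531 with an estimated correlation), interferon genes higher (20 of 23, 0.0484; 0.406) and cholesterol genes lower (18 of 24, 0.0484; 0.512), the last 2 called in 5 and 7 of 15 fits that each left out 1 library. In OL nuclei after injection neuron genes fell at 1 h (15 of 17, adjusted p = 0.0152; 0.679), called in 4 of 8 such fits, and heat shock genes at 6 h (10 of 14, 0.0387; 0.71), called in 4 of 8.

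At 16 h OPC nuclei given YM-CSF also had lower erythrocyte (5 of 5, adjusted p = 0.0121), unfolded protein response (14 of 18, 0.0149) and ribosomal protein genes (26 of 34, 0.0157) than with aCSF, each at 0.674 with an estimated correlation. With AM-CSF cholesterol (18 of 24, 0.000881), OPC (15 of 19, 0.00179), astrocyte (12 of 15, 0.00495), unfolded protein response (15 of 18, 0.0265), FGF and ERK feedback (14 of 16, 0.0272) and cell cycle genes (22 of 31, 0.049) were lower and glucocorticoid (16 of 17, 0.0265) and meningeal genes (7 of 9, 0.0322) higher than with aCSF, at 0.658 to 0.68 with an estimated correlation. Between the fluids endothelial genes were higher with YM-CSF (10 of 16, 0.000192) and ribosomal protein genes lower (26 of 34, 0.00865), at 0.924 with an estimated correlation. Each of these 13 calls was lost in at least 1 fit that left out 1 library. Ependymal genes were called in 0 of 11 contrasts by camera (smallest adjusted p 0.452).

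The contrasts of YM-CSF and AM-CSF with aCSF at 16 h share their controls. Their log2 fold changes correlated at 0.60, and 20 simulations with shared controls and no effect of either fluid gave 0.60, with the same sign in 69.1% of genes against 69.4% simulated. Their covariance was 1.04 against 0.99 simulated (SD 0.041). Over all genes the likeness of the 2 responses is thus near what shared controls alone give. These measures take all genes together, so they cannot exclude that some genes or lists answered both fluids.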
